A study of Caenorhabditis elegans with 2 samples.

How the data were processed

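Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole transgenic Caenorhabditis elegans hermaphrodites. Per the labels, the strain, OP489, carries an integrated transgene in which the nuclear hormone receptor NHR-232 has a GFP-FLAG tag at its C-terminus. Late embryos were taken 5 hours after the culture was synchronised by bleaching, and chromatin was fragmented by sonication. The text of the labels names an anti-GFP antibody, while their antibody field holds the name of the target. The 2 samples form 1 group, and the labels number them as biological replicates 1 and 2. The control experiment that the labels point to was not analysed here.

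The authors deposited peak lists in the ce11 and ce10 builds. For each build these were 1 list per replicate, 1 list of candidate regions called on the pooled replicates, and 1 list of the regions that passed the irreproducible discovery rate (IDR) procedure. The deposited signal value of each region is the authors' own, as their peak caller gave it. It was higher in the pooled lists than in those of single replicates, so it was used to rank and describe regions within a list, and between replicates only for the correlation fixed before the data were examined and for the replicate ratio of the mitochondrial regions, whose scales may differ. The deposited lists also hold a −log10 q value per region. The summit position, deposited as an offset in bp from the start of the region, was used to place each region on the genome. The aligner, the peak caller and their settings are not given in the sources used here. Read totals were not used here, so the sequencing depth of each replicate is unknown, and depth cannot be set against the differences between replicates.

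Results are from the ce11 lists, and coordinates are 1-based on ce11. The sequence of the WBcel235 assembly, which ce11 names, and its Ensembl release 115 annotation were used, and no ce11 region ran past the end of a chromosome of that assembly. Names of small RNA genes and of mitochondrial genes were taken from the RefSeq annotation of the same assembly. No coordinates were converted between builds. The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

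A region counted as found in a replicate when 1 of that replicate's strongest regions, as many as there are IDR regions, had its summit within 100 bp. The background was the pooled candidate regions that overlapped no IDR region, since these could have passed. A promoter ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Each summit received 1 of 5 classes, in the order noncoding RNA gene, promoter, exon, intron and intergenic. A gene was called bound when its promoter held the summit of an IDR region, and both genes were counted where promoters overlapped. The 24 gene lists were compared with all genes whose promoter held a candidate summit. Motifs and 6-mers were counted on both strands within 50 bp of the summit, against the same number of candidate regions from the lower-ranked part of the pooled list, matched on GC content.

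Shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the classes, chromosomes, lists, motifs or 6-mers of a family and a threshold of 0.05. Shares per chromosome were set against chromosome length with a two-sided exact binomial test. Correlations have permutation p-values from 100000 resamples. Intervals are 95% Wilson intervals and cover counting error only. All of these tests treat regions or genes as the units. Regions are not independent replicates, and with 1 group no test compares conditions.

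The steps were tested on simulated data. In the 6-mer search, all 50 6-mers planted in 20% of the regions were recovered, together with 28 to 36 other 6-mers per run. Of 5 runs with nothing planted, 0 gave a call. Simulated regions and controls both came from the lower-ranked part of the pooled list. These runs therefore cannot show how many calls arise where regions and controls differ in genomic class, as the IDR regions and other candidates do. For the gene lists, 234 of 300 planted enrichments were recovered (78%), where members of lists of at least 25 genes were given 6 times the weight of other genes, and 3 of 100 runs with nothing planted gave a call. The 8 lists with fewer genes in the background were not planted, so that share does not apply to them.

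The groups, tests, gene lists, motifs and rule for named genes were fixed before the data were examined. The rule named the genes whose promoters held the summits of the 20 strongest IDR regions, or otherwise the nearest protein-coding gene. It also named any noncoding RNA gene that held such a summit, up to 4 bound members of each list past the threshold, up to 10 bound nuclear hormone receptor genes, and nhr-232 and unc-119. The comparison with tRNA, snoRNA and snRNA genes, which took summits within 200 bp of such a gene, was chosen after seeing the data. Alternatives changed the build, the threshold, the overlap rule, the promoter window, the motif window and the background, or took the strongest regions of a single replicate. Others, chosen after seeing the data, left out mitochondrial regions or regions at small RNA genes.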

Results

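The data comprised ChIP-seq of GFP-tagged NHR-232 in late embryos of C. elegans, with 2 biological replicates and 1 group. NHR-232 belongs to the nuclear hormone receptors, a family of transcription factors that is greatly expanded in nematodes. The authors' IDR list held 519 regions with a median width of 470 bp, which covered 220 kb. Their signal values ran from 89.4 to 1294 with a median of 135, and their −log10 q values from 1.43 to 2.21. They were the 519 regions of highest signal among the 21094 candidate regions of the pooled list (2.46%). The separate lists held 20530 regions for replicate 1 and 22891 for replicate 2. In the ce10 files the IDR list held 668 of 20706 pooled regions.

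The first question was where in the genome the tagged receptor was recovered. Regions at genes for small structural RNAs made up 259 of the 519 IDR regions (49.9%). Genes for transfer RNAs (tRNAs), the adaptors of translation, lay within 200 bp of 194 summits (37.4%, 95% interval 33.3 to 41.6), against 192 of 20388 other candidate regions (0.942%), a 39.7-fold higher share. Genes for small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, lay within 200 bp of 54 summits (10.4%, interval 8.06 to 13.3), against 0.432% of the other candidates, a 24.1-fold higher share. Genes for small nuclear RNAs (snRNAs) lay near 12 summits (2.31%, interval 1.33 to 4.00), against 0.191%. The adjusted p-values of Fisher's exact test were 7.49e-216 for tRNA genes, 1.74e-49 for snoRNA genes and 3.18e-09 for snRNA genes. This comparison was chosen after seeing the data. The tRNA regions also had fewer unique sequences around their summits, where a median of 78.3% of 50-mers occurred once in the genome, against 100% at snoRNA regions.

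**Figure D1:**
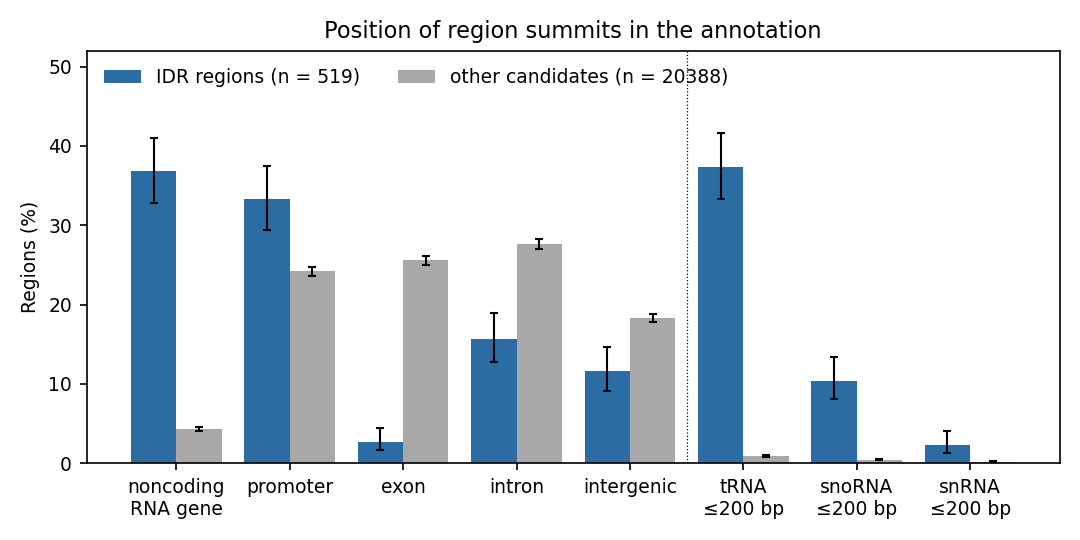
Share of region summits (percent) in each class of the annotation, for the 519 IDR regions in blue and the 20388 other candidate regions in grey, with 95% Wilson intervals as error bars. To the left of the dotted line each summit has a single class; to the right, summits within 200 bp of a tRNA, snoRNA or snRNA gene are counted, 37.4%, 10.4% and 2.31% of the IDR regions.

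The classes fixed before the data were examined used the gene bodies alone. The summits of 191 IDR regions lay inside a noncoding RNA gene (36.8%, interval 32.8 to 41), against 4.32% of the other candidates (adjusted p = 3.02e-113, Fisher's exact test). A further 173 lay in promoters of protein-coding genes (33.3%, against 24.2%, adjusted exact p = 4.76e-06). Exons held 14 IDR summits (2.70%) but 25.6% of the other candidates (adjusted exact p = 2.21e-45). Introns held 81 (15.6%, against 27.6%, adjusted exact p = 3.04e-10) and intergenic sequence 60 (11.6%, against 18.3%, adjusted exact p = 5.02e-05).

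Among all annotated nuclear genes of each kind, 202 of 612 tRNA genes had an IDR region within 200 bp (33%, interval 29.4 to 36.8). For snoRNA genes it was 52 of 346 (15%, interval 11.6 to 19.2), a lower share (adjusted p = 2.13e-09, Fisher's exact test). For snRNA genes it was 10 of 129 (7.75%, interval 4.26 to 13.7). The summits took different positions at the tRNA and snoRNA genes. The counts here are of genes, each with its nearest IDR summit, so neighbouring genes can share a summit. At tRNA genes the median summit was 12 bp downstream of the 5′ end (quartiles -12 and 41), and 121 of 202 were inside the gene (59.9%). At snoRNA genes the median summit was at -51.5 bp, upstream of the 5′ end (quartiles -68 and -41.5), and 48 of 52 were upstream (92.3%), with 2 inside the gene.

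**Figure D2:**
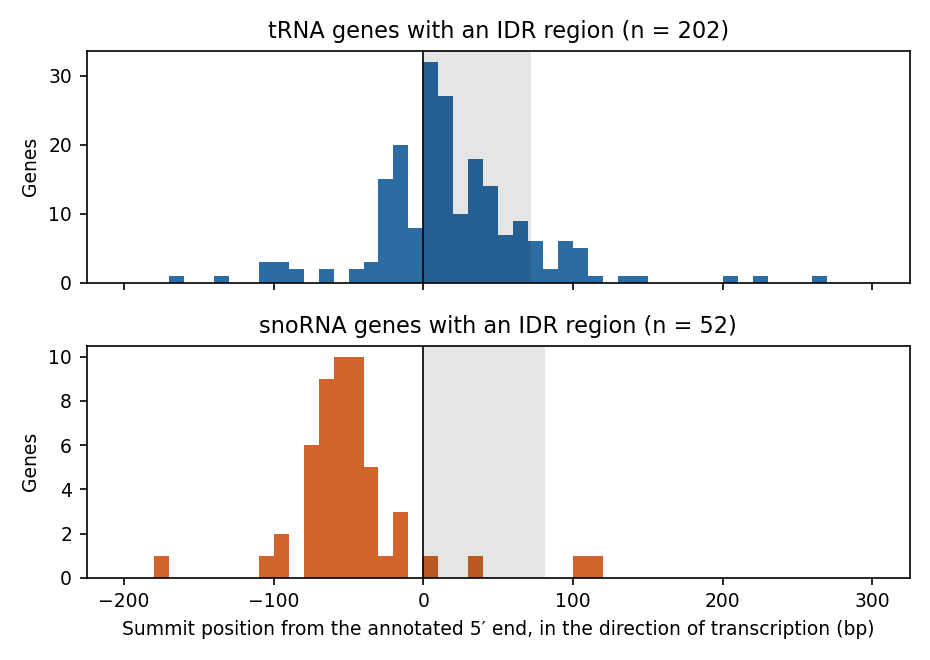
Distance in bp from the annotated 5′ end of each tRNA gene (202 genes) and snoRNA gene (52 genes) with an IDR region to the nearest IDR summit, with negative values upstream and a grey band for the median length of the genes plotted. The tRNA summits centre at 12 bp, within the gene, and the snoRNA summits at -51.5 bp.

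The tRNA and snoRNA shares also differed with the rank of the regions. In successive blocks of 100 regions from rank 1 to rank 500, tRNA regions made up 39%, 55%, 45%, 35% and 18%, and snoRNA regions 29%, 12%, 6%, 2% and 3%. The last 19 IDR regions, a small block, had 2 of each kind (10.5%). Among ranks 520 to 1000 of the pooled list, which had not passed the IDR procedure, tRNA regions made up 8.94%, and among ranks 10001 to 21094 they made up 0.532%. The median signal was 300.6 for the 54 snoRNA regions, 158 for the 194 tRNA regions and 112.2 for the 243 nuclear regions at none of these genes.

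**Figure D3:**
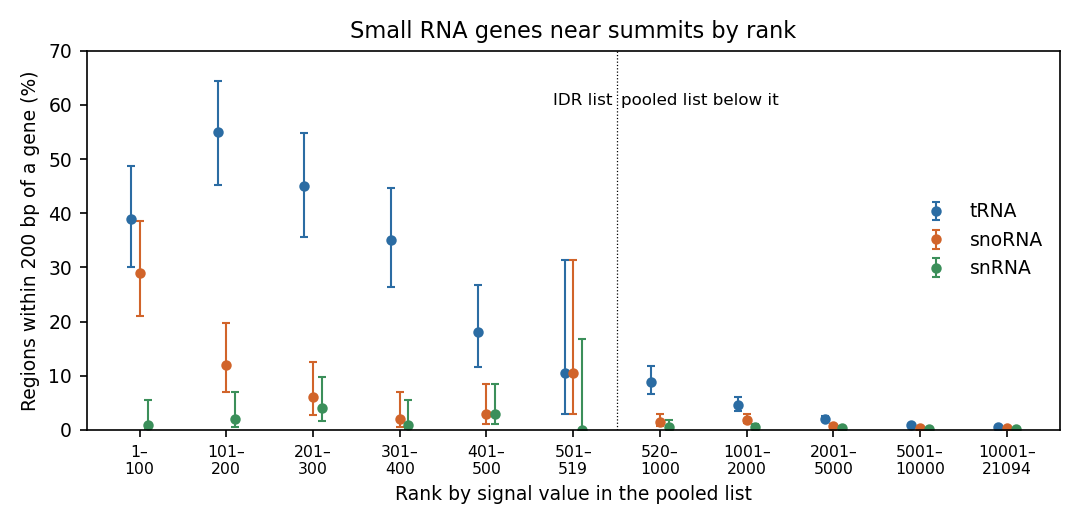
Share of regions (percent) within 200 bp of a tRNA, snoRNA or snRNA gene, in blocks of rank by signal value in the pooled list from the strongest at the left, with 95% Wilson intervals as error bars and a dotted line at the end of the IDR list. The tRNA share is 39% in the first 100 regions, 55% in the next 100 and 0.532% in ranks 10001 to 21094.

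Of the 20 strongest regions, 8 were near snoRNA genes, 7 were mitochondrial, 1 was at a tRNA gene, 1 was at another noncoding RNA gene and 3 were at promoters of protein-coding genes alone. The second strongest region (V 12303425 to 12303851, signal 863) had its summit in the snoRNA gene C51F7.4, inside the protein-coding gene frm-7. That summit also lay 71 bp upstream of another snoRNA gene, C51F7.3. The nearest 5′ end of a protein-coding gene was that of F55C5.17. The region at rank 14 had its summit in the snoRNA gene ZK994.7, inside pxn-1, which encodes a peroxidasin. Other snoRNA regions of this group were at rank 4 (II 11960643 to 11961042, intergenic, nearest gene W03C9.1, signal 797) and rank 5 (I 8259371 to 8259761, in the promoter window of the chemoreceptor gene sre-23, signal 777). Further ones lay in introns of cutl-18 (rank 7) and the MAP kinase gene mpk-2 (rank 15), near str-56 (rank 8), and at the promoter of mrps-28 (rank 12), which encodes a protein of the mitochondrial ribosome. The tRNA gene was the leucine tRNA C04A11.t1 (X 13665555 to 13665673, nearest protein-coding gene C04A11.5), with a signal of 610. The other noncoding RNA gene was F36H1.17 (region IV 11025925 to 11026398, nearest protein-coding gene hrg-5), with a signal of 587.

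Mitochondrial DNA held the strongest region in both replicates, inside ND5, which encodes a subunit of respiratory complex I (MtDNA 12216 to 12593, signal 1294). The other mitochondrial regions among the top 20 lay in COX1 at ranks 3 and 13, COX3 at rank 6, ND4 at rank 11, CYTB at rank 16 and COX2 at rank 18. Of 19 mitochondrial candidate regions, 17 passed the IDR procedure, and these covered 43.9% of the 13794 bp. Their median signal was 368, against 133 for nuclear IDR regions.

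The next question was how far the replicates gave the same regions. Of the 519 IDR regions, 360 were among the strongest 519 of both replicates (69.4%, interval 65.3 to 73.2), and 0 of 20388 other candidates were. Replicate 1 held 425 (81.9%) and replicate 2 held 440 (84.8%), with 145 in a single replicate and 14 in neither. Among the 259 strongest IDR regions, 256 were in both (98.8%). The IDR procedure selected regions for this property, so the overlap is not an independent test of it. Across 503 IDR regions matched in both replicates, signal correlated with Pearson's r = 0.858 on the log2 scale and Spearman's rho = 0.799. The permutation p was 1e-05 for each, the smallest that 100000 resamples can give, and the correlation is across regions, which are not independent replicates. Over the next 5000 regions of the pooled list, 3415 were matched. Their rho was 0.0219 (permutation p = 0.2) and r was 0.0469 (permutation p = 0.006), within a narrower range of signal. These regions were picked by pooled signal, which rose with both replicate signals together (at rank 2, 863 pooled against 418 and 440). Picking a narrow band of pooled signal can itself lower the correlation, so these values do not show whether weaker candidates replicate.

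**Figure D4:**
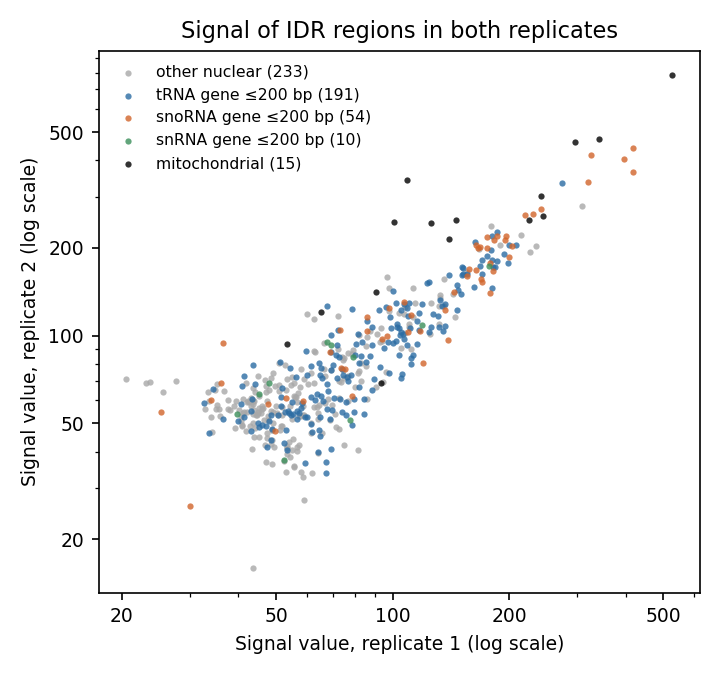
Signal value of each matched IDR region in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), coloured by the kind of gene at the region. Each point is 1 of 503 regions (Pearson's r = 0.858), and the mitochondrial region in ND5 ranks first in both.

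Promoters of protein-coding genes held the summits of 220 IDR regions (42.4%, interval 38.2 to 46.7), where regions that also lay in noncoding RNA genes are included. The other candidates had 5170 of 20388 there (25.4%, odds ratio 2.17, p = 1.12e-16, Fisher's exact test). With nuclear regions only, 207 of 502 were at promoters (41.2%). Among the 260 regions at no small RNA gene, which include the 17 mitochondrial ones, 63.5% were at promoters. Both settings were chosen after seeing the data. In all, 277 genes were bound, mitochondrial genes included, or 267 with nuclear regions only, and 64 regions lay in the promoters of more than 1 gene. The nuclear promoter regions at no small RNA gene numbered 152, at 208 genes, with a median summit at -255.5 bp from the 5′ end (quartiles -482 and -149). The strongest of these lay between mlcd-1 and idhg-1, a subunit gene of mitochondrial isocitrate dehydrogenase (III 4568609 to 4568884, signal 439.8). It was followed by a region at atx-2, the ataxin-2 homologue, and ecps-1 (III 10461179 to 10461475, signal 436), and by a region at K12H4.5 (III 8043806 to 8044122, signal 418).

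Of the 24 gene lists, heat shock proteins and their DnaJ-type partners formed the list that passed the threshold. Promoters of 6 of 25 such genes held an IDR region (24%, interval 11.5 to 43.4), against 5.01% of other genes (odds ratio 5.99, p = 0.00129, adjusted p = 0.0310, Fisher's exact test). The 4 bound members of highest signal were dnj-29 (signal 244), hsp-60, which encodes the mitochondrial chaperonin (signal 164), dnj-19 (signal 109) and dnj-5 (signal 106). The others were dnj-9 and hsp-6. The call was lost with the strongest regions of replicate 1 alone, that is without replicate 2 (16% against 4.60%, adjusted exact p = 0.642), with the 259 strongest regions (8% against 2.49%, adjusted p = 1) and with 500 bp promoters (21.1% against 5.18%, adjusted p = 0.369). Without replicate 1 it was kept (24%, adjusted exact p = 0.0406).

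No other list passed the threshold. Ribosomal protein genes had 6 of 57 bound (10.5%, interval 4.91 to 21.1, exact p = 0.0683, adjusted p = 0.820), histone genes 3 of 28 and oxidative phosphorylation genes 3 of 29. Nuclear hormone receptor genes had 3 of 62 bound (4.84%, adjusted exact p = 1), namely nhr-255 (X 15741977 to 15742163, signal 247, near a tRNA gene), nhr-47 (V 5505004 to 5505473, signal 109, shared with dnj-19) and nhr-142 (signal 94.2). The region that nhr-47 and dnj-19 share had its summit in the noncoding RNA gene C24G6.10. Chemoreceptor genes had 5 of 109, F-box and MATH genes 3 of 74, and C-type lectins 2 of 42. A single bound gene was found among 32 other developmental transcription factors, 35 cuticle collagens, 25 epidermis genes, 26 pan-neuronal genes, 25 neuropeptides, 13 glutathione S-transferases and 7 short-chain dehydrogenases. None was bound among 34 homeodomain factors, 15 intestine genes, 32 body wall muscle genes, 15 pharynx genes, 14 cilium genes, 25 germline genes, 16 cytochromes P450, 11 UDP-glucuronosyltransferases and 20 fatty acid genes. The upper 95% limits of these 0 counts ran from 10.2% for homeodomain factors to 25.9% for UDP-glucuronosyltransferases.

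Chromosomes X and V differed from the other candidates in their shares of IDR regions. The X chromosome held 129 (24.9%, interval 21.3 to 28.7) against 16.5% of the other candidates (adjusted p = 5.54e-06, Fisher's exact test), and chromosome V held 61 (11.8%, against 17%, adjusted p = 0.00306). Mitochondrial DNA held 17 IDR regions, and its 2 other candidates overlap these, so no test against candidates was possible. Against chromosome length, its 3.28% of IDR regions compared with 0.0138% of the genome (adjusted p = 4.59e-34, exact binomial test), a background that takes no account of how many copies of each molecule a cell holds. Chromosomes I, II, III and IV did not pass the threshold (adjusted exact p = 0.115, 0.118, 0.593 and 0.568). The X chromosome carries 276 of the 612 tRNA genes (45.1%), and 82 of its 129 regions were at tRNA genes (63.6%). Without the regions at tRNA genes, X held 47 of 325 regions (14.5%) against 16.2%, and the excess was lost (adjusted exact p = 0.627). On V the share stayed lower (13.8% against 17%, odds ratio 0.78) but no longer passed the threshold with fewer regions (adjusted exact p = 0.319). Each nuclear chromosome was divided into 3 equal parts, and the middle parts held 204 of 502 IDR regions (40.6%, against 29.0%, odds ratio 1.68, exact p = 4.00e-08).

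Short sequences that occur in tRNA genes were more frequent under the IDR summits, and none of the tested hormone receptor half-sites passed the threshold. ACCACT occurred in 21.8% of IDR regions against 4.43% of GC-matched candidates (adjusted p = 4.35e-14, Fisher's exact test), and GTTCGA, the core of the internal B box promoter element of tRNA genes, in 19.1% against 4.24% (adjusted p = 2.07e-11). In the 194 tRNA regions GTTCGA occurred in 38.7% against 6.19%. In the 54 snoRNA regions no 6-mer passed the threshold. In all, 268 6-mers passed the threshold, 144 more frequent and 124 less frequent in IDR regions, and many of them overlap. The controls were not matched on genomic class, and exons held 2.70% of IDR summits against 25.6% of the other candidates. These counts therefore cannot separate a sequence preference from a difference in class. Of the 15 fixed motifs, 0 passed, with 1 at an unadjusted p under 0.05 (GAGAGA, 15.8% against 11.2%, exact p = 0.0363, adjusted p = 0.455). In the tRNA regions alone, a subset chosen after seeing the data, CAGCTG passed with a lower share (0.515% against 6.19%, adjusted exact p = 0.0442). Within 100 bp of the summit, GAGAGA did pass (32.6% against 18.9%, adjusted exact p = 8.95e-06), but the control 6-mer TCCGAT also passed at that window, with a lower share in IDR regions (adjusted exact p = 0.00875). GAGAGA also passed against flanks of the same regions, which were not matched on GC content (adjusted exact p = 0.000815). The half-site AGGTCA occurred in 3.47% against 2.70% (adjusted exact p = 0.895) and AGTGCA in 5.01% against 3.85% (adjusted p = 0.895). In the tRNA regions AGGTCA occurred in 5.67% against 2.06% and AGTGCA in 2.06% against 5.15%. In the 243 nuclear regions at no small RNA gene, AGGTCA occurred in 1.65% against 2.47% and AGTGCA in 6.58% against 4.94%. None of these shares passed the threshold, and both subsets were chosen after seeing the data.

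Neither nhr-232 nor unc-119 had an IDR region. At nhr-232 (V 10256170 to 10258783) no list had a region within 2000 bp, and the nearest pooled candidate was 7216 bp away, while 31.7% of protein-coding genes likewise had no pooled candidate within 2000 bp. At unc-119 (III 10902641 to 10908935), the gene whose mutation the strain carries, 4 pooled candidates lay within 2000 bp, the strongest at rank 9322 of 21094 (signal 33.7). In the separate lists, the strongest region there was at rank 8955 of 20530 in replicate 1 and at rank 3167 of 22891 in replicate 2.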

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

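Settings that left out mitochondrial regions or regions at small RNA genes were chosen after seeing the data. Across the main results, 121 alternative values stayed on their side of the threshold or, for counts without a test, near the main count. So did 206 values for single lists or genes. Values past the threshold in both settings also kept their direction. Direction was not compared where neither value passed, and some of those values changed direction. C-type lectins, for example, had an odds ratio of 0.931 in the main setting and 1.95 with the 259 strongest regions. Among the main results, 11 further values moved, 5 no longer passed the threshold, 4 newly passed it and 1 reversed, and 2 of those for single lists newly passed. The heat shock list was at 8% with the 259 strongest regions (2.49% of other genes) and 21.1% with 500 bp promoters, where it no longer passed the threshold, and at 16 to 24% when 1 replicate was left out. The number of lists past the threshold was 0 with the 259 strongest regions and with 500 bp promoters, 0 to 1 when 1 replicate was left out, and 3 against all protein-coding genes, namely heat shock proteins, ribosomal proteins (7.5% against 1.36%, adjusted exact p = 0.00685) and, with a lower share, chemoreceptors (0.366% against 1.46%, adjusted exact p = 0.00208). The 259 strongest regions bound 137 genes, which follows from the smaller number of regions. Chromosome I, below the other candidates but not past the threshold in the main setting, passed it with the 259 strongest regions (12.7%) and without replicate 1 (13.9%, adjusted exact p = 0.0161), its range being 13.9 to 15% when 1 replicate was left out. Against chromosome length, III (17.7%) and IV (13.3%) passed the threshold. The share on V no longer passed with the 259 strongest regions (12.4%) or without tRNA regions (13.8%), and the excess on X turned to 14.5% without tRNA regions. Fixed motifs past the threshold numbered 2 within 100 bp (GAGAGA, more frequent, and the control TCCGAT, less frequent) and 2 against flanks (GAGAGA, more frequent, and TGATAA, less frequent), and 6-mers 120 with the 259 strongest regions, 99 within 25 bp, 595 against flanks and 72 without small RNA regions. The flanks were not matched on GC content (36.6%, against 50.3% under the summits). The cause of the other changes was not tested, and unknown read depth limits the ranking of weak regions.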

Other observations

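The tests of summit position, of subsets of tRNA, snoRNA and snRNA genes, of 6-mers in subsets of regions, of snoRNA copies alone, of random nuclear sets, of mitochondrial coverage and of the X share without tRNA regions were chosen only after the result was seen, as were the genes named in the next paragraph.

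Other noncoding RNA genes outside the tRNA, snoRNA and snRNA classes also lay at IDR regions. The RNA component of RNase P, rpr-1 (I 13463955 to 13464207), lay at a region of signal 258 at rank 91, and that of RNase MRP, mrpr-1 (II 7200233 to 7200418), at a region of signal 218 at rank 129. All 5 annotated srpr genes, which encode the RNA of the signal recognition particle, had an IDR region, with signals from 94.0 for srpr-3 to 257 for srpr-2.2. Of the 16 annotated 5S ribosomal RNA genes, 0 had an IDR region and 1 had a candidate region. Spliced leader RNA genes had an IDR region in 5 of 30 cases and other snRNA genes in 5 of 99, a difference that did not pass the threshold (adjusted p = 0.104, Fisher's exact test).

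Within the tRNA and snoRNA genes, no test of position in the genome passed the threshold. On X, 88 of 276 tRNA genes had an IDR region (31.9%), against 114 of 336 on the autosomes (33.9%, adjusted p = 0.605, Fisher's exact test). Of snoRNA genes inside a protein-coding gene on the same strand, 23 of 183 had one (12.6%), against 29 of 163 elsewhere (17.8%, adjusted exact p = 0.239). The 243 nuclear regions at no small RNA gene had CGCACA in 22.6% against 4.53% (adjusted exact p = 7.70e-06). The 133 of them with a summit in a promoter and in no noncoding RNA gene had TTGCAA in 21.8% against 0.752% (adjusted exact p = 1.41e-05). CGCACA also passed among all IDR regions (14.5% against 3.28%). Of the 260 regions at no small RNA gene, mitochondrial ones included, 63.5% were at promoters, against 25.3% of candidates. A difference in genomic class may therefore enter the CGCACA shares too.

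For the enrichment at tRNA and snoRNA genes, a possible source in reads shared between gene copies is argued against at snoRNA genes, where a median of 100% of 50-mers near the summit occurred once in the genome, and stays open at tRNA genes, where it was 78.3%, between the bounds set. Recovery of highly transcribed chromatin stays open. The upper 95% limit of ribosomal protein promoters, 21.1%, met the bound set against it by lying below the 33% of tRNA genes. The bases of these shares differ, being 57 promoters with a candidate region and all 612 tRNA genes. That bound also rested on a single list with no transcription values. Against all protein-coding genes the same list passed the threshold (7.5%, upper limit 15.4%, against 1.36%, adjusted exact p = 0.00685). Occupancy at RNA polymerase III promoters is consistent with the summits inside tRNA genes and at -51.5 bp from snoRNA genes, and GTTCGA lay within 150 bp upstream of 36.5% of bound snoRNA genes against 3.40% of the others (p = 6.35e-11, Fisher's exact test). The median distance of GTTCGA from the snoRNA 5′ end was 15 bp (quartiles 12 and 19.5), nearer the gene than the median summit. Within 50 bp of the summits of the 54 snoRNA regions, no 6-mer passed the threshold against GC-matched candidates. GTTCGA was therefore not shown to be more frequent at snoRNA summits than at candidates. Of other genes that RNA polymerase III transcribes, rpr-1, mrpr-1 and 5 of 5 srpr genes had a region. Of the genes for 5S RNA, 0 of 16 had one, and uniqueness of their copies was not tested. Spliced leader genes, which this polymerase does not transcribe, had a region in 5 of 30 cases. The tally is incomplete, since the 1 annotated Y RNA gene was not counted and other snRNA genes (5 of 99) were not split by polymerase. With 1 group the design compares no conditions, so these values describe where the regions lie and not what recruits the receptor, and whether the control or other tagged factors give the same regions was not analysed here.

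The mitochondrial regions may reflect DNA recovered with the chromatin rather than receptor bound to it. Their median log2 ratio of replicate 1 to replicate 2 of -0.63 lay inside the central 95% of single nuclear regions (-0.90 to 0.68), a bound that is wrong for a median of 15 regions. Of 10000 random nuclear sets of the same size 0% had as low a median, but this decides nothing, because the mitochondrial regions lie on 1 molecule, several overlap, and 2 single libraries are compared on separate signal scales. The regions covered 43.9% of the mitochondrial genome, between the bounds set for whole-genome recovery and for discrete sites, so these cannot be told apart. The control, which could separate them, was not analysed here.

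The excess on the X chromosome may follow from the tRNA genes, since the X share was 14.5% without the regions at tRNA genes, against 16.2% of the other candidates. No other explanation for the excess was tested.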
